A study of Rattus norvegicus with 4 samples.

How the data were processed

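HSC-T6 rat hepatic stellate cells were sequenced as 4 total RNA libraries, 2 from untreated cells and 2 from cells treated with ginsenoside Rk1, grouped by the treatment and titles in the labels. Per the labels' protocols, RNA was extracted with Trizol, accepted above a set integrity number, and made into cDNA libraries with the VAHTS Universal V6 kit for Illumina. Reads were handled with HISAT2 and HTSeq, per the submitters' processing notes. Their versions, the strand setting, the handling of reads that match several places and any read filter are not given in the sources used here. The authors deposited 1 table of raw counts per Ensembl gene, with gene symbols, descriptions and positions in Rnor_6.0 per the file headers, and no normalisation had been applied to these counts. The deposited counts could divide or drop reads between overlapping genes and near-identical copies, and 132 tested genes carry a symbol that stands on several identifiers. A count table of summed exons does not separate transcripts or strands of a gene.

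Symbols and coordinates were taken from the table itself. The reference gene table on assembly GRCr8 was not used, because its Ensembl column was empty. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12316 of 32883 genes. Libraries were scaled by TMM (factors 0.994 to 1.01), and CPM use the scaled library totals. The main test was edgeR's quasi-likelihood F-test, two-sided, with group as the only term and 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.059. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Means and SDs of CPM are over 2 libraries.

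In all, 34 gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. The 31 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, two-sided, adjusted over the 31 lists, with the correlation estimated from the data as an alternative. At the preset correlation 11 lists were higher and 11 lower. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.111, with 10 lists at an unadjusted p under 0.05. By fry 21 passed, but fry asks whether list members change at all, and camera whether they change more than other genes. The estimated-correlation form rests on the 2 residual degrees of freedom, so it could hardly pass any list, whatever the correlation of its genes. For endoplasmic reticulum chaperones the estimate was 2.7e-05, under the preset 0.01, yet the unadjusted camera p went from 1.6e-18 to 0.011. Members were also adjusted over the list alone. The values of 1 of the 31 lists, which did not pass, and of some list members are not reported. Named genes were the 12 with the largest change in each direction among called genes with a mean of at least 5 CPM, groups that did not overlap and a symbol that is no placeholder, the genes named in the title, and up to 4 members of each list with the smallest adjusted p. Genes named because a count of 5 or fewer needed it, and those said to be singled out, were chosen after their values were seen.

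The 2 libraries of a group were compared before averaging. Their counts differed by more than sampling noise (chi-square per degree of freedom 4.47 untreated and 4.52 with Rk1), so neither pair is a single library deposited again. Log CPM correlated across genes at 0.991 within both groups and at 0.983 to 0.985 between groups. Library totals ranged from 18008586 to 20430930 counts, and the 10 most abundant genes held 5.77% to 5.87% of each. The floor of 3 counts covers counting error only, as reads carried no molecular identifiers in the sources used here. The steps were tested on simulated data for the comparison of Rk1 with untreated cells, with 200 of 12316 genes changed. All 200 were drawn from genes with a mean count of at least 100, so recovery at lower counts was not measured. The test recovered 56% of genes at the smallest fold simulated, 80% at 1.5-fold and 100% at 2-fold and 3-fold. Of 180 calls, 12 were unchanged genes, and 1 of 31 lists was called when no gene had been changed. Simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely.

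Alternatives were DESeq2, limma-voom, edgeR with robust dispersions, other scalings, other filters, a replicate block, mitochondrial genes left out, stricter thresholds, and each library left out in turn, where the lone library of a group is assumed to vary like the other group. Chosen after seeing the data were the matching of list members through gene descriptions, the ferroptosis-restraining list without Dhcr7, 7 additional gene families, and a fit without symbols on several identifiers. The planned test of annotation terms was not run because the table pairs no genes with terms. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.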

Results

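Gene expression was measured by RNA sequencing in HSC-T6 cells, an immortalised rat hepatic stellate cell line. Stellate cells are the liver cells that lay down collagen when they turn into myofibroblasts. The 4 libraries comprised 2 of untreated cells and 2 of cells treated with ginsenoside Rk1, a saponin of processed ginseng, and n = 2 per group holds for every value given here. The labels give no dose, duration or vehicle. Total counts assigned to genes were 20430930 and 18175053 in the untreated libraries and 18008586 and 18125005 in the Rk1 libraries, and 3 counts in a library correspond to between 0.147 and 0.167 CPM, the count scaled to library size. Of 32883 annotated genes, 17410 had a count and 12316 were abundant enough to be tested. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

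The single comparison of the design asked which transcripts differ after Rk1, with the series title naming glycolysis, ferroptosis and 4 genes as its subject. Most tested genes in the lists for glycolysis, other hypoxia-inducible genes, cholesterol and fatty acid synthesis and lysosomes rose with Rk1. Most of those for fibrillar matrix and endoplasmic reticulum (ER) chaperones fell. Falls also numbered 9 of 15 contractile, 26 of 38 mitotic and 26 of 32 interferon-stimulated genes, but 6 contractile genes fell without untreated replicate 1, untreated replicate 2 or Rk1 replicate 2. Only 15 mitotic genes fell without untreated replicate 2 and 18 without Rk1 replicate 1, and 10 interferon-stimulated genes with robust dispersions. Of 30 NF-kB targets and chemokines 11 fell and 2 rose. Each list of this paragraph passed camera, a gene set test, at its preset correlation, and none passed with an estimated correlation (adjusted p = 0.111 to 0.287). The latter form rests on 2 residual degrees of freedom, so failing it says little about any 1 list. In edgeR's quasi-likelihood test, 1422 genes were higher and 1289 lower at a Benjamini-Hochberg adjusted p under 0.05, which is 22.0% of the genes tested. Most changes were small, with a median of 1.26-fold among the called genes, and 86 genes were higher and 152 lower by at least 2-fold. The first principal component held 58.0% of the variance and separated the treated from the untreated libraries. The count fell to 1712 genes by DESeq2, with 859 higher and 853 lower, and to 1795 without untreated replicate 2, with 853 higher and 942 lower.

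The series title names Hk2, Acsl4, Lpcat3 and Alox5. Hk2, which encodes the hexokinase that commits glucose to metabolism in many proliferating cells, rose from 80.3 ± 0.0054 to 158 ± 8.9 CPM (mean ± SD), a 1.97-fold change (log2 fold change 0.98 ± 0.05 SE, adjusted p = 6.0e-05). Lpcat3, which loads polyunsaturated fatty acids into phospholipids, rose 1.51-fold (0.59 ± 0.04, adjusted p = 1.4e-04) from 191 ± 0.82 to 288 ± 1.6 CPM. Acsl4, which activates arachidonic acid for that step, rose 1.43-fold (0.52 ± 0.04, adjusted p = 2.8e-04) from 310 ± 7.1 to 445 ± 8.8 CPM. Alox5, which encodes arachidonate 5-lipoxygenase, had 0 counts in all 4 libraries, which allows up to 0.167 CPM in the shallowest library, so a difference was not detectable at this depth. In Rnor_6.0 coordinates, Hk2 (ENSRNOG00000006116) lies on chromosome 4 at 113559427 to 113610243, minus strand, and Lpcat3 (ENSRNOG00000012269) on chromosome 4 at 157181795 to 157222996, plus strand. Acsl4 (ENSRNOG00000019180) lies on chromosome X at 113596239 to 113659944 and Alox5 (ENSRNOG00000012972) on chromosome 4 at 148398892 to 148446303, both on the minus strand. Counts are summed over the exons of each gene, and the annotated Emg1 gene overlaps Lpcat3 on the opposite strand, so some reads there could belong to either. As a list the 3 tested genes were higher (camera adjusted p = 6.2e-13), but adjusted p = 0.128 with an estimated correlation, and all 3 passed when adjusted over the list alone. Because the study chose these genes, the list is not independent evidence of its direction.

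**Figure D1:**
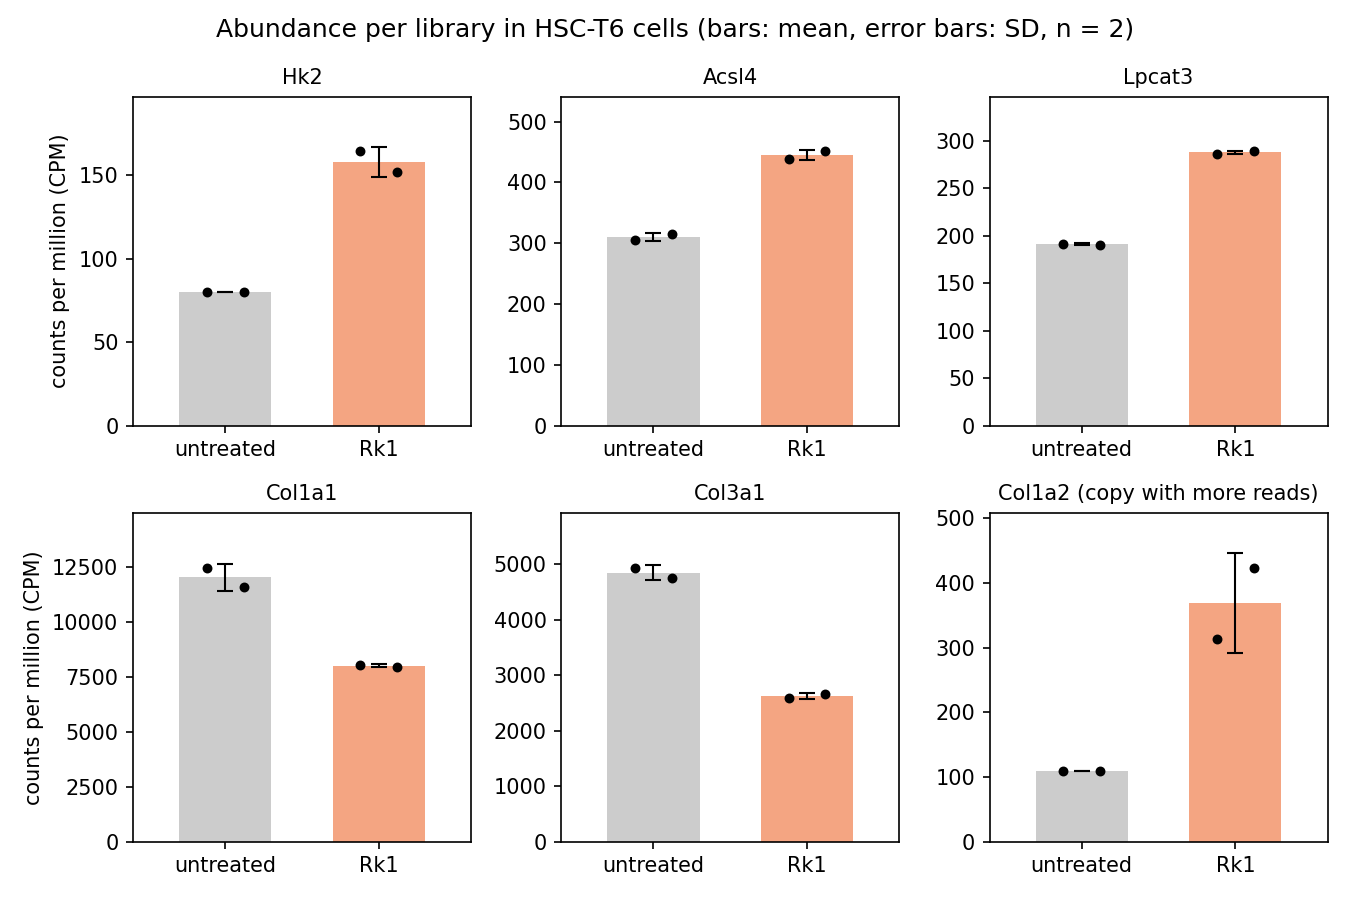
Abundance in CPM (vertical axes, each from 0) of Hk2, Acsl4 and Lpcat3 (upper row) and of Col1a1, Col3a1 and the Col1a2 copy with more reads (lower row) in untreated and Rk1-treated cells, with bars for the mean, error bars for the SD and a point for each of the 2 libraries. Hk2 went from a mean of 80.3 to 158 CPM, while Col1a1 went from 12050 to 8017 CPM.

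Most transcripts of the glycolytic pathway rose. Of 21 glycolysis genes tested, 15 rose and 0 fell (17 rose when adjusted over the list alone), with a median log2 fold change of 0.63. The rising genes included Slc16a3, a lactate exporter (1.13 ± 0.06), Aldoc, an aldolase (1.09 ± 0.06), and Pgk1, phosphoglycerate kinase (0.86 ± 0.04, from 856 ± 14 to 1555 ± 64 CPM). The list was higher by camera (adjusted p = 6.3e-32), with adjusted p = 0.128 with an estimated correlation. Of 17 genes induced by hypoxia outside glycolysis, 14 rose and 0 fell, and the same numbers passed when adjusted over the list alone. Their median was 0.72. Bnip3, a mitophagy receptor, rose 3.22-fold (1.69 ± 0.05), Bhlhe40, a transcriptional repressor, rose 3.31-fold (1.73 ± 0.06), and Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.94 ± 0.06. By camera the adjusted p was 9.9e-39, and adjusted p = 0.128 with an estimated correlation. Vegfa, a hypoxia-inducible gene singled out after its values were seen, was at 140 ± 19 and 158 ± 12 CPM and did not pass (0.18 ± 0.09, adjusted p = 0.22).

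Most lipid synthesis genes rose. Of 25 genes of cholesterol synthesis and uptake, 24 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.75. Insig1, a sterol-regulated ER protein, rose 2.95-fold (1.56 ± 0.05), the sterol reductase gene Tm7sf2 rose 3.18-fold (1.67 ± 0.10), and Msmo1 (1.13 ± 0.04), Acat2 (1.10 ± 0.05) and Sqle (0.98 ± 0.05), all enzymes of the pathway, rose as well. For this list camera gave an adjusted p of 4.4e-79, and adjusted p = 0.111 with an estimated correlation. Of 17 genes of fatty acid synthesis, 14 rose and 0 fell (14 and 1 when adjusted over the list alone), with a median of 0.56. Scd, which makes monounsaturated fatty acids, rose 2.58-fold (1.37 ± 0.05), Acss2 by 0.93 ± 0.05, Fasn, fatty acid synthase, by 0.72 ± 0.04 and Acly by 0.65 ± 0.04. That list was higher by camera (adjusted p = 2.2e-31, and adjusted p = 0.111 with an estimated correlation). Of 10 targets of the oxysterol receptor LXR and sterol export genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.57. Npc1 (0.97 ± 0.05) and Npc2 (0.65 ± 0.05), which move cholesterol out of lysosomes, and Abca1, a cholesterol exporter (0.77 ± 0.15), were among them, as was Lpcat3, a gene named in the title. The list passed camera with an adjusted p of 2.9e-07, and adjusted p = 0.204 with an estimated correlation. Of 19 genes of beta-oxidation and PPAR signalling, 3 rose, among them Ppard (0.33 ± 0.05) and Fabp5 (0.24 ± 0.04), and 0 fell, also when adjusted over the list alone. That list did not pass camera (adjusted p = 0.272) but passed by fry (0.040), which asks only whether members change at all.

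Genes that promote and genes that restrain ferroptosis, an iron-dependent death by lipid peroxidation, both included more risen than fallen members. Among 19 promoting genes, 6 rose and 1 fell, also when adjusted over the list alone, with a median of 0.09. The risen genes included Sat1 (1.07 ± 0.06), a polyamine catabolic enzyme, Lpcat3, Acsl4 and the transferrin receptor Tfrc (0.34 ± 0.06). By camera the adjusted p was 7.9e-04, and adjusted p = 0.150 with an estimated correlation. Among 23 restraining genes, 10 rose and 1 fell, also when adjusted over the list alone, with a median of 0.14. The risen genes included Scd, the quinone reductase Nqo1 (0.86 ± 0.05) and glutathione reductase Gsr (0.49 ± 0.05), and Hspb1 fell by 0.18 ± 0.05. Camera gave that list an adjusted p of 8.8e-08, and adjusted p = 0.128 with an estimated correlation. The list as fixed holds Dhcr7 (0.84 ± 0.05), whose enzyme consumes a sterol that protects against lipid peroxidation and so does not belong on the restraining side. Without it, a choice made after the data were seen, 9 of 22 rose and 1 fell (camera adjusted p = 3.7e-06, and adjusted p = 0.135 with an estimated correlation). Without Rk1 replicate 1, 0 members of either list fell, and 2 restraining genes fell without Rk1 replicate 2. Gpx4, which detoxifies lipid peroxides, and the cystine transporter gene Slc7a11 were singled out after their values were seen. Gpx4 rose by 0.27 ± 0.06 (adjusted p = 0.016), and Slc7a11 did not pass, at 98.2 ± 12.3 and 83.6 ± 13.7 CPM (adjusted p = 0.21). Of 23 targets of NRF2, the transcription factor of the oxidant response, 12 rose and 0 fell, also when adjusted over the list alone, with a median of 0.16, and 1 fell without Rk1 replicate 2. They included heme oxygenase Hmox1 (0.98 ± 0.08), Abcc4 (0.70 ± 0.04) and malic enzyme Me1 (0.61 ± 0.05). For this list camera gave an adjusted p of 9.0e-10, and adjusted p = 0.150 with an estimated correlation. Nqo1, Gsr and other genes stand in more than 1 of these lists, and Acsl4 and Lpcat3 are named in the title.

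Most fibrillar matrix genes fell with Rk1. Of 22 fibrillar matrix genes, 17 fell and 2 rose (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.44. Col3a1, a fibrillar collagen, fell from 4845 ± 131 to 2627 ± 46 CPM (-0.88 ± 0.03), tenascin Tnc by 1.01 ± 0.05, Col6a1 by 1.04 ± 0.06 and the collagen chaperone Serpinh1 by 0.60 ± 0.03. Col1a1, singled out after its values were seen, fell by 0.59 ± 0.04 from 12050 ± 615 to 8017 ± 68 CPM. The 2 genes that rose, the crosslinking enzymes Plod2 and Loxl2 (both 0.19), were not called without untreated replicate 1 or without untreated replicate 2, and 1 was called without Rk1 replicate 1. The list passed camera with an adjusted p of 2.7e-24, and adjusted p = 0.150 with an estimated correlation. Col1a2 is not listed under that symbol, and after the data were seen it was found by its description on 2 gene identifiers of chromosome 4. The copy with more reads (31534225 to 31569151) rose from 109 ± 0.27 to 369 ± 78 CPM (1.75 ± 0.13, adjusted p = 1.7e-04). The other copy (29529854 to 29564768) fell from 26.1 ± 13.2 to 9.98 ± 0.84 CPM (-1.39 ± 0.31, adjusted p = 0.019), and since near-identical copies can divide reads, each value is uncertain. Of 14 matrix proteases and inhibitors, 7 fell and 1 rose, also when adjusted over the list alone. Adamts5 (-1.36 ± 0.10), Adamts1 (-0.95 ± 0.05) and Timp1 (-0.37 ± 0.03) were among those that fell. The list median was -0.28 (camera adjusted p = 1.7e-05, and adjusted p = 0.170 with an estimated correlation). The gene that rose, Timp2, was not called without untreated replicate 2, where 0 members rose, and 2 members rose without Rk1 replicate 2.

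Of 15 contractile genes that mark myofibroblasts, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.26, and 6 fell without untreated replicate 1, untreated replicate 2 or Rk1 replicate 2. Tagln, an actin-binding protein, fell 7.18-fold from 16.9 ± 0.35 to 2.35 ± 0.015 CPM (-2.84 ± 0.12), Tpm1 by 0.89 ± 0.06, Smtn by 0.66 ± 0.05 and Cald1 by 0.39 ± 0.04. Acta2, the smooth muscle actin that defines activated stellate cells and was singled out after its values were seen, fell by 2.44 ± 0.39 (adjusted p = 0.0047) from a low level of 73 and 56 counts to 16 and 6 counts. By camera the adjusted p was 4.0e-08, and adjusted p = 0.215 with an estimated correlation. Of 15 targets of the mechanosensitive coactivators YAP and TAZ, 8 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.29. They included the matricellular genes Ccn2 (-2.74 ± 0.13) and Ccn1 (-1.67 ± 0.09), Amotl2 (-0.67 ± 0.06) and Crim1 (-0.57 ± 0.08). For this list camera gave an adjusted p of 3.9e-08, and adjusted p = 0.128 with an estimated correlation. TGF-beta response genes went both ways. Of 22 tested, 6 fell, among them Ccn2, Ltbp2 (-1.28 ± 0.08) and Tgfb2 (-0.70 ± 0.07), and 4 rose, among them Tgfb1 (0.46 ± 0.05), with 6 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.149). Only 2 rose without untreated replicate 1. Of 16 PDGF and other growth factor genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone), including Igf1 (-1.42 ± 0.23), Hbegf (-0.73 ± 0.10), Pdgfd (-0.47 ± 0.06) and Pdgfc (-0.42 ± 0.08). The median was -0.25 (camera adjusted p = 0.0023, and adjusted p = 0.170 with an estimated correlation). Of 10 tested genes on the list fixed for quiescent stellate cells, Ecm1 (0.47 ± 0.07) and Nes (0.31 ± 0.08) rose and Gfap (-1.88 ± 0.32) fell, also when adjusted over the list alone. The list did not pass (adjusted p = 0.911, with a median of 0.04 and a mean of -0.12). Whether Nes marks quiescence in these cells was not tested, so its rise is not read as such. The rise of Nes was not called when any 1 of the 4 libraries was left out.

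**Figure D2:**
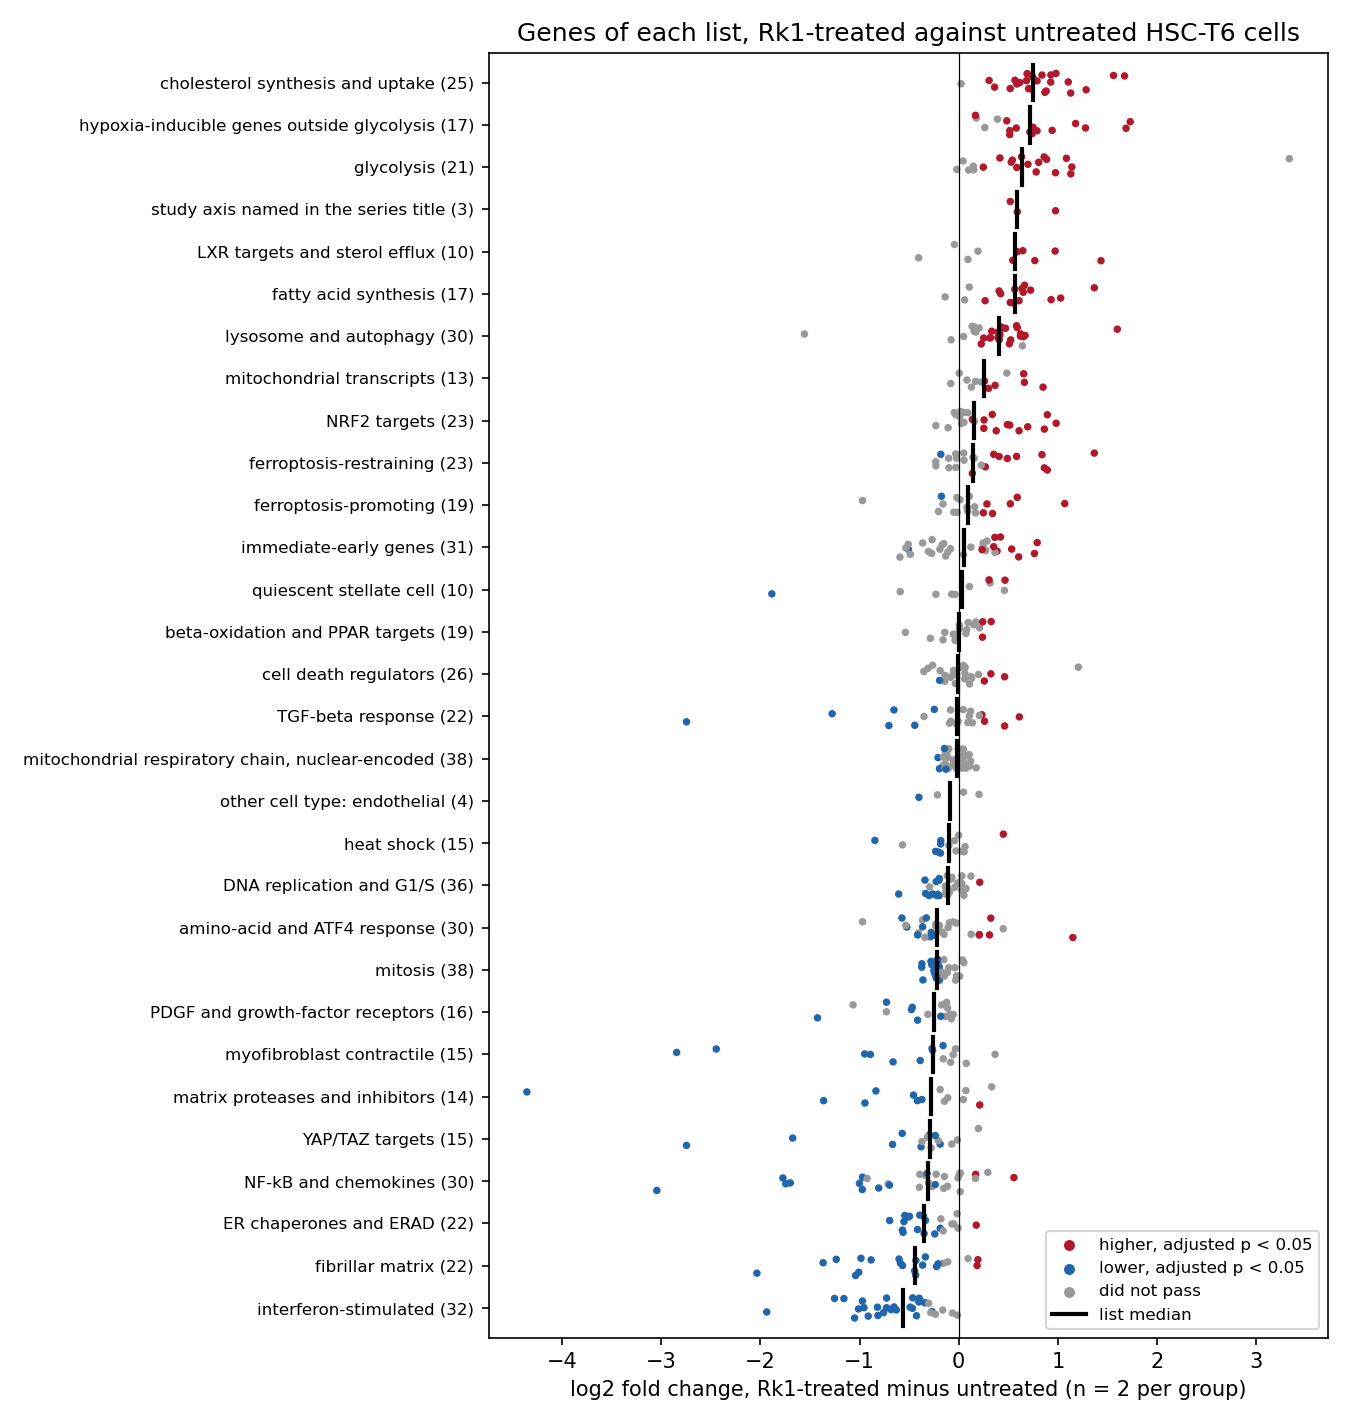
Log2 fold change, Rk1-treated minus untreated, of each tested gene (points) in 30 of the 31 lists with at least 3 tested members (rows, number tested in parentheses), with a black bar at the list median. Red and blue points passed an adjusted p of 0.05 and grey points did not, and the medians run from -0.56 for interferon-stimulated genes to 0.75 for cholesterol synthesis and uptake.

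Some chemokine and interferon-stimulated transcripts fell with Rk1. Of 30 NF-kB targets and chemokines, 11 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.31. Il33, an alarmin cytokine, fell 8.24-fold from 46.3 ± 0.79 to 5.61 ± 0.37 CPM (-3.04 ± 0.08). Cxcl12 (adjusted p = 4.1e-05), Cx3cl1 (-1.74 ± 0.18) and Ccl5 (-1.70 ± 0.20), which attract leukocytes, also fell. Nfkbia and Nfkb1 rose, and 1 member of the list rose when any 1 library was left out. The list passed camera with an adjusted p of 1.2e-07, and adjusted p = 0.204 with an estimated correlation. Of 32 interferon-stimulated genes, 26 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.56. The antiviral genes Mx1 (-1.93 ± 0.20, from 708 ± 121 to 185 ± 60 CPM), Isg20 (-1.25 ± 0.10), Oasl (-0.97 ± 0.08) and Bst2 (-0.76 ± 0.07) were among them. The libraries of a group differed from each other in these genes, with list medians, after centring each gene on its mean over the 4 libraries, of 0.38 and 0.17 on the log2 scale untreated and -0.41 and -0.16 with Rk1. With robust dispersions 10 of these genes fell and Mx1 was not called (adjusted p = 0.092). By camera the adjusted p was 2.5e-20, with adjusted p = 0.287 with an estimated correlation and 0.098 by fry.

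Most chaperones of the ER fell. Of 22 ER chaperone and ER-associated degradation genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.35. Hspa5, the major ER chaperone, fell from 1796 ± 33 to 1212 ± 25 CPM (-0.57 ± 0.04), Hsp90b1 by 0.56 ± 0.04, calreticulin Calr by 0.50 ± 0.03 and Creld2 by 0.70 ± 0.05, and the gene that rose, Derl1 (0.18), was not called when any 1 library was left out. For this list camera gave an adjusted p of 6.3e-18, and adjusted p = 0.111 with an estimated correlation. Of 30 genes of amino acid supply and the ATF4 response, 8 fell and 4 rose, also when adjusted over the list alone. Pck2 (-0.57 ± 0.06), the serine synthesis enzyme Phgdh (-0.33 ± 0.04) and Mthfd2 (-0.52 ± 0.09) fell, and Ddit4, an mTORC1 inhibitor, rose by 1.15 ± 0.13. With robust dispersions Mthfd2 (adjusted p = 0.068) and Ddit4 (0.074) were not called. The median was -0.22 and camera called the list lower (adjusted p = 0.011), with adjusted p = 0.673 with an estimated correlation and 0.399 by fry. That call was lost without untreated replicate 2 (adjusted p = 0.353) and without Rk1 replicate 1 (0.492). The count that fell was 14 without untreated replicate 1 and 17 without Rk1 replicate 2, where 1 and 2 rose. The libraries of a group differed in these genes about as much as the groups did, with list medians, centred as for the interferon-stimulated genes, of -0.016 and 0.20 untreated and -0.20 and 0.028 with Rk1. Replicate 2 stood above replicate 1 in both groups, and Rk1 below untreated at either number. With a replicate block the list passed camera at the preset correlation (adjusted p = 1.1e-04) and 17 genes fell. Nothing in the labels says that the numbers mark batches. Of 15 heat shock genes, 6 fell, among them the small chaperone Cryab (-0.85 ± 0.09) and Hsp90ab1 (-0.21 ± 0.04), and Bag3 rose (0.45 ± 0.06), also when adjusted over the list alone. The list did not pass (adjusted p = 0.078), although it passed without untreated replicate 2 (0.0082), and 3 genes fell without untreated replicate 1 and 2 without Rk1 replicate 1.

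Mitotic transcripts that fell did so by a small amount. Of 38 mitotic genes, 26 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.22. The examples Ube2c (-0.37 ± 0.05), Pbk (-0.37 ± 0.06), Ttk (-0.36 ± 0.06) and Kif20a (-0.28 ± 0.04) act in spindle assembly or mitotic exit. The list passed camera with an adjusted p of 5.8e-09, and adjusted p = 0.276 with an estimated correlation, and 15 genes fell without untreated replicate 2 and 18 without Rk1 replicate 1. Of 36 genes of DNA replication and the G1/S transition, 11 fell, led by cyclin D Ccnd1 (-0.61 ± 0.06) and thymidine kinase Tk1 (-0.34 ± 0.04), and 1 rose, also when adjusted over the list alone. The gene that rose, Rrm2, was not called without untreated replicate 2 or without Rk1 replicate 1. The median was -0.11 (camera adjusted p = 0.0023, and adjusted p = 0.318 with an estimated correlation). Of 26 regulators of apoptosis and other cell death, Bax (0.32 ± 0.05), Bad (0.26 ± 0.06) and Bmf (0.46 ± 0.12) rose and Mlkl fell (-0.19 ± 0.06), with 3 and 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.935). Without untreated replicate 2 or Rk1 replicate 1, 1 rose, and the number that fell was 0 without untreated replicate 1 or Rk1 replicate 1 and 2 without untreated replicate 2 or Rk1 replicate 2. Of 31 immediate-early genes, 9 rose, among them Ier3 (0.76 ± 0.06), the phosphatase Dusp1 (0.79 ± 0.09) and Klf10 (0.35 ± 0.04), and Jun fell (-0.51 ± 0.05), with 11 and 2 adjusted over the list alone. The list did not pass (adjusted p = 0.148), although it passed without untreated replicate 2 (0.042). In that list 5 rose without untreated replicate 1 or Rk1 replicate 1, and 4 fell without untreated replicate 1 or Rk1 replicate 2.

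Most lysosomal transcripts rose. Of 30 lysosome and autophagy genes, 21 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.40, and 1 fell without Rk1 replicate 2. Gpnmb, a lysosome-associated glycoprotein, rose 3.03-fold, and the protease Ctsd (0.67 ± 0.04) and the membrane protein Lamp1 (0.65 ± 0.05) rose as well. By camera the adjusted p was 1.6e-24, and adjusted p = 0.150 with an estimated correlation. Of 13 mitochondrially encoded transcripts, 6 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.26. They included Mt-nd5 (0.66 ± 0.04), Mt-cyb (0.65 ± 0.06), Mt-nd4l (0.85 ± 0.08) and Mt-nd2 (0.30 ± 0.03), while Mt-co1 was at 13506 ± 91 and 13550 ± 482 CPM. The mitochondrial share of counts was 3.11% and 3.24% in the untreated and 3.60% and 3.68% in the Rk1 libraries. Several of these genes overlap a neighbour, and the camera adjusted p was 1.8e-07, and adjusted p = 0.150 with an estimated correlation. Of 38 nuclear-encoded respiratory chain genes, 4 fell (Ndufs8, Ndufa5, Atp5f1b and Atp5f1a, by 0.13 to 0.21) and 0 rose, with 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.324). The count that fell was 0 without untreated replicate 1 or untreated replicate 2, 1 (with 1 that rose) without Rk1 replicate 2 and 9 with upper-quartile scaling.

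Markers of other liver cells were mostly under the filter. Of 16 hepatocyte markers only transferrin Tf was tested (-0.09 ± 0.05, adjusted p = 0.22). Of 18 macrophage and leukocyte markers, Cd14 rose (0.31 ± 0.05, 43.6 ± 2.2 to 54.1 ± 0.28 CPM, not called without untreated replicate 2) and Cd68 did not pass (0.31 ± 0.29). Of 13 endothelial markers, 4 were tested and Egfl7 fell (-0.40 ± 0.12), a call lost when any 1 library was left out, and the list did not pass (adjusted p = 0.749). Of 9 biliary markers, both that were tested fell, Sox9 (-1.74 ± 0.17) and Spp1, osteopontin, from 1705 ± 11 to 1287 ± 5.5 CPM (-0.41 ± 0.03). The other 7 were under the filter, so Sox9 and Spp1 are not read as a sign of biliary cells. In these 4 lists the counts were no different when adjusted over the list alone.

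Among called genes with a mean of at least 5 CPM and a symbol that is no placeholder, the 12 with the largest rise included several already described (Bhlhe40, Bnip3, Tm7sf2, Gpnmb, Insig1 and Scd). The others were Ndufa4l2, a hypoxia-inducible respiratory chain subunit (5.07-fold, 2.34 ± 0.16), the metal-binding metallothioneins Mt1 (4.02-fold) and Mt2A (2.59-fold), the mitochondrial adenylate kinase Ak4 (2.62-fold), Nxph4 (2.50-fold) and Map3k7. The gene annotated as Map3k7 on chromosome 9 (114022137 to 114079089) had 52 and 18 counts untreated and 244 and 259 with Rk1 (2.94 ± 0.32), so its untreated libraries differed by over 2-fold. The 12 with the largest fall under the same limits were Il33, Tagln, Ccn2, the guanylate-binding protein Gbp1 (4.21-fold), Mx1, Nt5c1b (3.58-fold), the fibril-associated collagen Col14a1 (3.54-fold), carbonic anhydrase Car1 (3.48-fold), the NKG2D receptor gene Klrk1 (3.43-fold), Cx3cl1, Sox9 and Ccl5. Klrk1 was not called with robust dispersions (adjusted p = 0.052). Mt1 and Map3k7 overlap an annotated gene on the opposite strand and Tm7sf2 and Tagln one on the same strand, and the strand setting of the counting is not given in the sources used here, so these values are uncertain. The same holds for Gpx4, Gsr, Abcc4, Acss2, Npc1, Abca1, Col3a1, Timp1, Tgfb2, Pdgfc, Pdgfd, Hsp90b1, Kif20a, Lamp1, Ndufs8, Atp5f1b and Egfl7, which overlap another annotated gene.

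**Figure D3:**
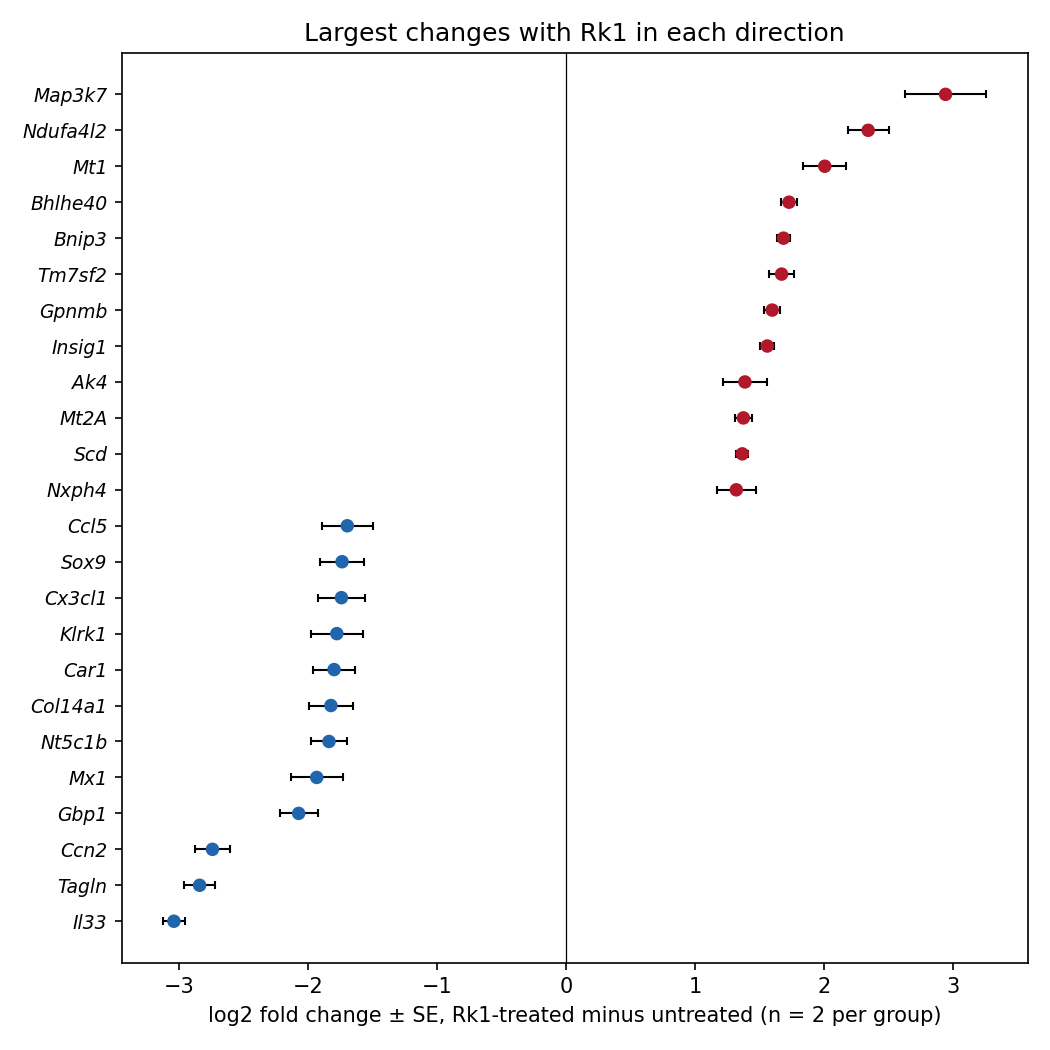
Log2 fold change with its standard error (horizontal axis, Rk1-treated minus untreated, n = 2 per group) of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue) that passed the test, with a mean of at least 5 CPM and a symbol that is no placeholder, which leaves out the Col1a2 copies. The values run from -3.04 for Il33 to 2.94 for Map3k7.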

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

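The fit without symbols on several identifiers and the matching through descriptions, also of list medians, were chosen after seeing the data. The main count of genes differing between Rk1-treated and untreated HSC-T6 cells was 2711. DESeq2 called 1712 (859 higher, 853 lower; 1693 also called by edgeR), an adjusted p under 0.01 left 1226 (665 and 561), a change of at least 2-fold left 238 (86 and 152), and a test against a 1.5-fold change left 147 (69 and 78); the cause of the difference for DESeq2, which gave 478 genes no adjusted p, was not tested, and the others are stricter by construction. Leaving out 1 library, and so having fewer samples, gave 1795 to 2186 genes, 853 to 1160 of them higher and 902 to 1026 lower, with the lowest total and the 853 without untreated replicate 2. Robust dispersions, other scalings, other filters, limma-voom, mitochondrial genes left out and symbols on several identifiers left out gave 2543 to 3061. Of the 2711 genes, those tested in each fit (2547 at the least, with at least 5 CPM in 2 libraries) included 0 that changed sign. The 2 groups did not overlap in CPM in any of the 2711, so leaving out a library could hardly reverse a sign. With upper-quartile scaling 43.5% of calls were higher, against 52.5%. Hk2, Acsl4 and Lpcat3 were called in all of these fits at an adjusted p under 0.05 with no minimum fold; Acsl4 changed by less than 1.5-fold and none of the 3 reached 2-fold. Of the 132 genes that the naming rule gave, 17 changed their call in some setting, with 50 losses, 3 gains and 0 reversals in 2101 comparisons; these leave out Plod2, Loxl2, Timp2, Derl1 and Rrm2, which also lost calls without 1 library. Of the 31 lists, 22 passed camera, and 0 with an estimated correlation (10 at an unadjusted p under 0.05), a form that rests on 2 residual degrees of freedom and could hardly pass any. By fry, which asks whether members change at all rather than more than other genes, 21 passed. These lacked the ATF4 (adjusted p = 0.399) and interferon-stimulated (0.098) lists and added beta-oxidation (0.040). With 1 library left out 21 to 23 passed: the ATF4 list was lost without untreated replicate 2 (0.353) or Rk1 replicate 1 (0.492), and heat shock (0.0082) and immediate-early genes (0.042) were added without untreated replicate 2. Members matched through descriptions changed 0 list calls. The test of annotation terms was not run. Genes below about 0.167 CPM are out of reach at this depth, and genes under the filter were not tested even where they had counts. Changes of the smallest fold simulated were recovered in 56% of genes, all of them well counted, so recovery at lower counts is not known.

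With a replicate block, the count of genes differing between Rk1-treated and untreated HSC-T6 cells was 3214, 1676 higher and 1538 lower, and 0 list calls changed, while the ATF4 genes that fell numbered 17 against 8. The labels give the libraries a shared number and nothing more, and whether it marks a batch stays open. Differences between replicates 1 and 2 correlated at 0.059 between the groups across genes, over only 2 pairs. The second principal component (22.3% of the variance) set both replicates 1 (13.5 and 12.4) apart from both replicates 2 (-12.4 and -13.6), and the third (19.7%) did not. With 4 libraries only these 2 components remain after the first, so such a split could arise without a shared replicate effect. List medians stood higher in replicate 2 of both groups for the ATF4 list, but not for the interferon-stimulated list.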

Other observations

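Of the tests in the 3 patterns weighed at the end, those of reads moved between copies and of a lower sterol level alone were chosen only after the result was seen.

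The families in this and the next paragraph were defined after seeing the data. All 3 metallothionein genes tested rose (log2 fold changes 1.37 to 2.01), though Mt1m had only 6 and 4 counts untreated and 13 and 16 with Rk1. All 4 ferritin light chain loci rose too (median 1.07), and these are near-identical copies that can share reads. Of 21 subunits of the V-ATPase, the proton pump of lysosomes, 16 rose and 0 fell (median 0.41), among them Atp6ap1 (0.71 ± 0.04). Atp6v1a, Atp6v1h and Atp6v0d1 also stand in the lysosome list. No set test is given for these families, since they were picked from the values such a test would use.

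Of 9 genes of proline and serine synthesis, 5 fell and 0 rose (median -0.28). Pycr1, the last enzyme of mitochondrial proline synthesis, fell by 1.32 ± 0.06. Of 20 cytosolic tRNA synthetases 9 fell and 0 rose (median -0.24), and of 76 ribosomal protein loci 31 fell and 1 rose (median -0.14). Of 24 MHC class I and peptide loading genes 12 fell and 0 rose (median -0.40). The libraries of a group stood apart in the last of these families, with medians of log2 CPM centred on each gene's mean of 0.28 and 0.098 untreated and -0.29 and -0.072 with Rk1, and in the tRNA synthetases, with 0.053 and 0.17 untreated and -0.14 and -0.081 with Rk1. In proline and serine synthesis these medians were 0.085 and 0.19 untreated and -0.17 and -0.099 with Rk1. Some members, among them Phgdh, Psat1, Psph and Gars, also stand in the ATF4 list, and Tap1, Psmb8 and Psmb9 in the interferon-stimulated list. These families are therefore not wholly separate from those lists.

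Symbols on several identifiers behaved differently from the rest. Of 91 such genes with a mean count of at least 20, 14 (15.4%) differed by more than 2-fold between replicates of a group, against 143 of 11527 (1.24%) with a symbol of their own (Fisher's exact test, two-sided, p = 1.6e-11, across genes, which are not independent replicates). An example is Tnks2, with 5 and 96 counts in the untreated and 7 and 339 in the Rk1 libraries at ENSRNOG00000052664.

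The rise of Col1a2 stood against the fall of Col1a1 and Col3a1. Reads moved from 1 annotated copy to the other would leave the sum of the 2 unchanged, but the summed counts rose by 1.48 ± 0.13 on the log2 scale. The share on the other copy was 24.5% and 13.3% untreated and 3.26% and 2.17% with Rk1. The sum holds only counted reads, and the handling of reads that match both copies is not given. A change in the reads dropped at the copies therefore stays open. Reads of an overlapping annotated gene are argued against by 0 other genes overlapping the rising copy, and a trend with exonic length or abundance by a change of 1.74 ± 0.13 after it was removed. Sequence missing from the assembly or incomplete models at this locus stay open, as does a response to Rk1, which was not tested further, since untreated Col1a1 was at 12050 CPM and the Col1a2 copies at 136 CPM.

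Of the sterol synthesis and uptake genes 24 of 25 were higher with Rk1, as were 6 of 10 on the LXR list. Both lists passed camera at the preset correlation and neither with an estimated one (adjusted p = 0.111 and 0.204). A trend with length or abundance explained 1.0% of the variance, and the lower of the 2 list medians was 0.59 ± 0.20 (bootstrap SE) after its removal. The bootstrap resampled the genes of a list, which may not vary independently, and leaves out the spread between libraries. A lower cellular sterol level alone predicts lower LXR targets and stays open. The median of the LXR list without Lpcat3 was 0.54 ± 0.27, just over 2 SE above 0, which with an SE over genes does not decide it. With Arl4c added the median was 0.37 ± 0.26, which is within 2 SE of 0. Arl4c was found by its description, at a low-count locus annotated as a pseudogene (-0.56 ± 0.20, adjusted p = 0.083). Npc1 and Npc2, which are in the LXR list, are also lysosomal genes. Sterol held in lysosomes could raise synthesis and lysosomal genes together, which was not tested by any measurement of sterol.

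Of the glycolysis genes 15 of 21 were higher with Rk1, as were 14 of 17 other hypoxia-inducible genes. Both lists passed camera at the preset correlation and neither with an estimated one (adjusted p = 0.128 for each). The lower of the 2 list medians was 0.67 ± 0.13 (SE from resampling genes) after the length and abundance trend was removed. That trend therefore does not account for the rise. The lowest median over 4 scalings of the libraries was 0.60 ± 0.13. Those scalings moved the median of all genes only between -0.026 and 0.0075, so this outcome could hardly have differed. It shows only that the choice among them does not matter. A shared response to Rk1 may be behind both lists, as a hypothesis. Oxygen supply, cell density and medium at harvest are not in the labels and could differ between the groups, so they stay open.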
